A study of Mus musculus with 10 samples.

How the data were processed

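Single-cell transcriptomes were measured in the brains of healthy mice at embryonic days 12.5 and 15.5 and postnatal days 0, 3 and 6. Per the labels, the forebrain was taken at every stage, the hindbrain at E12.5 and the pons at the later stages, which gives 10 libraries with 1 library per region and stage. The E12.5 hindbrain was grouped with the pons libraries because the labels assign it to the same joint annotation. Per the labels' protocols, tissue was dissected under a stereoscope and dissociated with a papain kit, and droplet libraries were made with the Chromium 3' version 2 chemistry, which captures the 3' ends of polyadenylated transcripts with a unique molecular identifier (UMI).

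The deposited matrices hold UMI counts per gene and cell, which the authors made with Cell Ranger 2.0.1 or 2.1.1 on the mm10 build, per the submitters' processing notes, without stating which library had which version. A filter on genes, UMIs and mitochondrial share was applied by the authors before annotation, per the deposited description of the metadata columns. The authors' metadata also give, per cell, the deposited UMI count, the percent of UMIs from mitochondrial genes, a cluster label from clustering each library alone (with some clusters marked as left out of later work), a later updated label and, for all libraries of a region together, a joint label. The deposited UMI count of every annotated cell equalled the sum of its matrix column. The matrices list 27998 genes, of which 56 symbols are shared by more than 1 identifier; counts of different identifiers were not merged. Between 3305 and 10821 annotated cells per library held 18304026 to 55242132 UMIs, with a median per cell of 2975 to 6629 UMIs. Columns of per-sample values not matched to a sample numbered 0.

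The authors' labels were collapsed into 15 classes by their words. The clusters the authors left out (0.0% to 16.15% of the annotated cells of a library by the first annotation) were set aside. The later updated labels leave out more in 3 libraries, 66.6% of the E15.5 pons (5559 of 8353 cells), 39.9% of the E12.5 hindbrain and 20.7% of the E12.5 forebrain, so that alternative also removes those cells. Shares of cells carry exact (Clopper-Pearson) binomial intervals at the 95% level, which cover counting error only. Trends of shares over stages were tested by an exact permutation of stages within each region (14400 arrangements, two-sided, statistic the mean of both within-region Spearman rho), and region differences by an exact paired sign-flip test over stages, whose smallest two-sided p is 0.0625, with Benjamini-Hochberg adjustment over classes.

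Raw counts were summed per library and class, since cells are not replicates. A class entered a fit from libraries with at least 20 of its cells. edgeR 4.0.16 in R 4.3.3 (TMM normalisation, filterByExpr, robust quasi-likelihood test) gave the region difference with stage as a factor, the slope per stage step (E12.5, E15.5, P0, P3, P6 in order) with region as a factor, and the difference between the slopes of the regions. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over genes. With 1 library per region and stage, the error of a region difference is its variation between stages, and every p-value measures only the spread between these libraries. Log2 values are given with a standard error computed as the absolute log2 value over the root of the F statistic of its test. It is not a reliable error where a region was at 0 counts. CPM values are the summed counts scaled to a common library total. Where every library of a region was at 0, the fold was computed against a floor of 3 counts over the region's libraries and is given as a lower bound. Where a region held 1 to 3 counts, the ratio is given with its counting interval.

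Classes differ in how cleanly the authors' labels hold them. Each of the 178 clusters kept was ranked by fold over the other clusters of its library, and 21 had more markers of another class than of their own among the top 10 genes. These are called led by markers of another class below. In the largest of them (1558 cells, E12.5 forebrain) this was 1 marker against 0, so the rule is a coarse one. None of these was in the oligodendrocyte precursors, astrocytes, microglia and macrophages, endothelial cells, oligodendrocytes or pericytes. In the progenitors they held 25.7% of the cells (6 of 24 clusters) and in the inhibitory neurons 19.4% (4 of 19 clusters). They held 31.3% of the intermediate progenitors (3 of 10 clusters) and 28.7% of the excitatory neurons (5 of 18 clusters), classes that enter the shares and class levels only, and 2.1% to 7.4% of the ependymal cells, other neurons and vascular leptomeningeal cells. Progenitors and inhibitory neurons were fitted as planned and, after the data were seen, again without these clusters. RNA from other cells was measured per class and library by the markers of other classes, as a share of their level in the rest of the library. For progenitors, neurons, oligodendrocyte precursors and astrocytes these were markers of immune, vascular, leptomeningeal and choroid plexus cells only. Doublets with other neural cells were not measured by them. The E12.5 hindbrain and E15.5 pons had under 5 such markers for progenitors, excitatory and inhibitory neurons, and there the median share of the class in its other libraries stood in. The share was taken over markers of at least 20 CPM in the rest of the library. A gene was counted as within that level where its CPM was at most 2 times this share of its CPM in the rest. This had to hold in every library of the side where the gene was higher. For slopes that side was the libraries at or after the median stage for rising genes, and at or before it for falling ones. A gene above the level in any of these libraries was not counted as within it.

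Gene lists fixed before the data were examined were tested with fry (limma 3.58.1), which asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes, and as an alternative with camera and an estimated correlation. The lists were HOX genes, forebrain patterning factors, hindbrain and midbrain patterning factors, S phase, G2M phase, fetal heterochronic, myelin, synaptic, astrocyte maturation, cholesterol synthesis, dissociation stress, homeostatic microglia, developmental phagocytic microglia, blood-brain barrier, chromatin and histone H3, pediatric brain tumour and mitochondrially encoded genes. A list was tested where at least 5 of its genes were. Named genes followed a rule fixed at the same time. Per class and comparison it took the 3 largest increases and 3 largest decreases with an adjusted p under 0.05 and an average of at least 32 CPM, for region with the same direction in every stage. It added the 2 called members with the largest change in each direction of a list given as an example, and fixed genes that included Pdgfra, Olig2, Hoxa3, Hoxb3, Mki67 and Top2a. Gene positions come from GENCODE M21 on GRCm38, the assembly that mm10 names.

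The fits were tested on simulated data with 200 changed genes in each of 3 simulations per class, on the real means and library sizes. With each gene's dispersion on the fitted trend, 3.0% to 4.7% of region calls and 2.0% to 5.0% of stage calls were false. With gene-wise dispersions, 5.6% (endothelial cells) to 14.9% (inhibitory neurons) of region calls were false, so region counts can hold more false calls than the threshold names. For stage, the share with gene-wise dispersions was 4.1% to 8.9% in the progenitors, astrocytes, microglia and endothelial cells, but 9 of 15 calls in the inhibitory neurons and 4 of 6 in the oligodendrocyte precursors. In that setting a 2-fold region difference was recovered for 38.7% (inhibitory neurons) to 85.0% (endothelial cells) of genes, and a slope of 1.5-fold per step for 0.3% (oligodendrocyte precursors) to 74.3% (microglia and macrophages).

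Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, the later updated labels, a minimum of 50 cells, doublets left out by Scrublet (scanpy 1.11.5 in Python 3.11.15), counts thinned to the smallest library, other stage or region terms, and each stage left out in turn. Scrublet marked 0.02% to 0.06% of cells in the P3 and P6 forebrain, the E12.5 hindbrain and the E15.5 pons, where it did not work, and the cells with the top 5% of doublet scores were left out instead as an alternative added after the data were seen. The joint labels, the clusters the authors left out, the clusters named above and a term for the series of library names were also added then. No doublets were removed in the main comparisons.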

Results

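The libraries were made as a reference of normal cell types of the developing forebrain and pons, in which the origins of childhood brain tumours can be sought. There are 2 regions and 5 stages with 1 library each, and between 3086 (pons P0) and 10487 (forebrain E12.5) annotated cells per library after the authors' left-out clusters were set aside. Median depth was lowest in the E12.5 forebrain (2975 UMIs per cell) and highest in the P6 pons (6629 UMIs). Single libraries were not tested against each other, and errors of fitted values come from the variation between stages or about a slope. Xist reached 1007.4 to 2413.6 CPM in the whole libraries of forebrain E12.5 and P0, hindbrain E12.5 and pons P6 and at most 0.8 CPM in the other libraries, while the Y-linked Ddx3y was at 0 in those 4 and at 41.4 to 97.3 CPM in the others. These genes stood alike in both regions at E12.5, E15.5 and P3 and opposite at P0 and P6.

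The first comparison was of cell classes over stages. Neurons made up most cells of the embryonic hindbrain and pons, and astrocytes and the oligodendrocyte lineage were named from P0 on. Inhibitory neurons were 46.45% of the cells of the E12.5 hindbrain (95% interval 45.00% to 47.90%) and 54.28% of the E15.5 pons (53.17% to 55.38%), and 3.86% at P0. The authors' later annotation leaves out 1446 of these 2139 cells at E12.5 and 2979 of 4302 at E15.5, and the shares among the cells it keeps are 21.89% and 47.35%. In the forebrain they were 20.23% at E12.5 and 5.42% at P0, where the authors left out a further cluster of 188. No cluster bore an astrocyte label at E12.5 or E15.5 in either region, while astrocytes were 18.32% of the P0 forebrain, 23.98% of the P0 pons and 35.59% of the P6 forebrain (34.08% to 37.12%). Oligodendrocyte precursors reached 21.72% in the P3 pons and 12.85% in the P3 forebrain. In the P3 pons 461 of the 1227 formed a cycling cluster with 0 precursor markers among its top 10 genes, 73.3% of them named glial progenitors in the joint labels, while cycling clusters of the P3 forebrain (273 cells) and P6 pons (442 cells) with that same joint name were counted as progenitors. Oligodendrocytes rose to 17.04% of the P6 pons (15.97% to 18.14%) and 5.69% of the P6 forebrain.

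Of the classes tested, 8 rose over stages and 2 fell by the exact permutation test. The shares of a library sum to a whole, so a fall of neurons by itself lifts the shares of other classes. These trends are therefore not independent results, and rises in share need not be rises in cell number. Astrocytes (mean rho 0.92, adjusted p = 0.0097), oligodendrocytes (0.93, adjusted p = 0.0097), endothelial cells (0.95, adjusted p = 0.0097), oligodendrocyte precursors (0.77, adjusted p = 0.0397) and microglia and macrophages (0.78, adjusted p = 0.0379) were among those that rose, exact permutation test, 5 stages in each of 2 regions. Pericytes (0.85, with vascular smooth muscle clusters in the pons at P0 and P6), ependymal cells (0.79) and vascular leptomeningeal cells (0.78) rose as well. Inhibitory (-0.92) and excitatory neurons (-0.75) fell. Clusters whose labels name neither kind were counted as other neurons. Among them were 138 and 167 cells of the P3 forebrain, with Tac1 and Sst among their top 10 genes. In the P0 pons they were 198 and 213 cells, both with Neurod1 there. The falls of inhibitory and excitatory neurons can follow this naming. Progenitors, at 47.34% of the E12.5 forebrain, 2.58% of the P0 forebrain and 16.24% of the P6 forebrain, did not pass (mean rho -0.50, adjusted p = 0.245, exact permutation test). The later annotation gives 35.63% in the E12.5 forebrain. It gives 30.45% in the E12.5 hindbrain and 28.88% in the E15.5 pons, against 13.40% and 8.11% by the first. A share of 0 means that no cluster bore the label in that library, and in the forebrain at P6 this was so of excitatory and inhibitory neurons alike (0 of 3886 cells). Counting error does not bound a share that labels set. A cluster of 141 cells that the authors left out there had globin genes, Sst and Npy among its top 10 genes. Dissociation and the authors' filters can set such shares. None of the 10 trends kept its call in every omission of a stage; without P0, P3 or P6 none passed (for astrocytes adjusted p = 0.071, 0.097 and 0.057, exact permutation test).

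**Figure D1:**
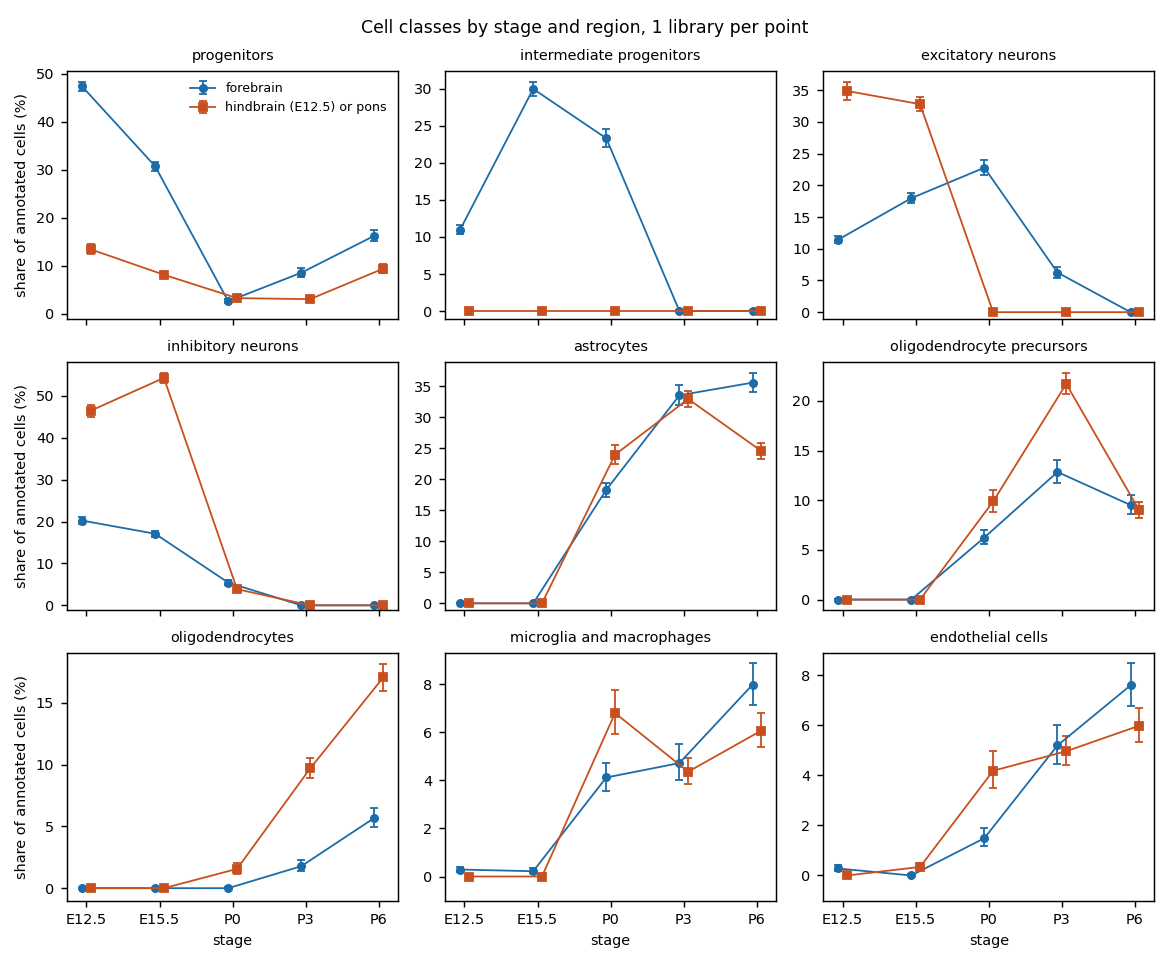
Share of annotated cells (%) in 9 classes by stage, with circles for the forebrain and squares for the hindbrain (E12.5) or pons, 1 library per point, and bars for the exact 95% binomial interval. Astrocytes are at 0 in both regions at the embryonic stages and at 18.32% to 35.59% from P0 on, while inhibitory neurons go from 54.28% in the E15.5 pons to 0 at P3, where no cluster bore that label.

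Between regions, no class passed the exact sign-flip test, whose smallest two-sided p of 0.0625 lies above the threshold. The largest difference was that of progenitors, 21.08% of the forebrain cells on average against 7.43% of the hindbrain or pons cells. They were lower there at 4 of 5 stages (-13.65 ± 14.22 percentage points, SD over stages, exact p = 0.125). The later annotation gives higher shares of them in the E12.5 hindbrain and E15.5 pons. Intermediate progenitors averaged 12.85% of the forebrain cells and 0% of the hindbrain or pons cells, a difference of -12.85 ± 13.57 percentage points (SD over 5 stages, higher in the forebrain at 3 stages, exact p = 0.25). The 0 of the P3 forebrain among these values rests on the authors' left-out clusters, 16.15% of that library, which bore the name (501 and 115 cells). That of the P6 forebrain follows naming too. A cluster of 631 cells there, 55.9% named inhibitory intermediate progenitors in the joint labels, was counted as progenitors. In the hindbrain and pons no cluster bore the name. Clusters with a neuronal progenitor label, such as 262 cells at E12.5 with Neurod4 among their top 10 genes, were counted as progenitors. Pericytes were higher in the hindbrain or pons at 4 of 5 stages (3.86% against 3.04%, exact p = 0.125), and oligodendrocytes averaged 5.66% there against 1.49% in the forebrain (exact p = 0.25). The pericyte class of the pons includes vascular smooth muscle clusters, 46 cells at P0 and 205 of the 333 at P6. No forebrain cluster bore that label, so the pericyte difference can follow the naming.

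The second comparison asked which genes differ between regions within a class. Oligodendrocyte precursors, the dividing cells that give rise to myelinating oligodendrocytes, differed between regions in transcription factors of regional identity at P0, P3 and P6. Dlx2, a homeobox factor of the ventral forebrain, stood at 45 CPM in the forebrain and at 0 counts in the pons (at least 114-fold lower, SE of log2 0.54, n = 3 stages, adjusted p = 0.00027, edgeR), and Dlx5, of the same family, was at least 32.8-fold lower. The pons cells held more Irx3 (log2 5.65, SE 0.35), Irx5 (38.2 CPM against 1 forebrain count, ratio 39.0 to 8678 by counting error) and Irx1 (2.48, SE 0.23), and Hoxa2, a gene of hindbrain segments, was at least 31.6-fold higher. Pdgfra, the growth factor receptor that marks the class, stood at 797 CPM in the pons and 615 CPM in the forebrain and did not pass (log2 0.23, SE 0.27, adjusted p = 0.80), nor did Olig2 (0.44, SE 0.21, adjusted p = 0.44).

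In the oligodendrocyte precursors 79 genes were higher in the pons and 112 in the forebrain, of 11102 tested over 3 stages (edgeR, adjusted p under the threshold). Outside the patterning factors, Ggct (log2 3.15, SE 0.21) and Gjc3, a gap junction gene of the oligodendrocyte lineage (2.70, SE 0.23), were the largest increases in the pons that the naming rule took, and Igfbpl1 (-3.91, SE 0.27) and the cyclin Ccnd2 (-2.49, SE 0.34) the largest decreases. Of 13 forebrain factors tested, 12 were lower in the pons (13 adjusted over the list alone; fry adjusted p = 0.033, adjusted p = 0.10 with an estimated correlation). Markers of inhibitory neurons, which share Dlx genes with that list, were lower in the pons for 4 of 5 (median log2 -7.45), and so was the 1 marker of excitatory neurons tested. Of 9 hindbrain and midbrain factors, 5 were higher (7 adjusted over the list alone; fry adjusted p = 0.023, adjusted p = 0.14 with an estimated correlation). Of 11 myelin genes, 4 were higher in the pons, among them Mobp (at least 72.0-fold) and Mag (log2 4.04, SE 0.53), and the list did not pass (fry adjusted p = 0.13). Mobp and Mag stood at 10.9% and 4.01% of their level in the rest of the library. The pons cells of P3 include the cycling cluster of 461 cells, which has no counterpart in the forebrain precursors, so differences can follow it. The gene count was 447 without the P3 stage and 93 without P0, 60 with no stage term and 986 with the joint labels.

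Astrocytes were compared at P0, P3 and P6. The forebrain factors Lhx2 (92.7 against 0.258 CPM, log2 -8.24, SE 0.22, adjusted p = 1.1e-05, edgeR) and Emx2 (-6.53, SE 0.57) were lower in the pons in each of 3 stages. Cyp26b1, an enzyme that breaks down retinoic acid, was 149-fold higher in the pons (log2 7.22, SE 0.29), with Irx5 (6.47, SE 0.31), Irx3 (5.87, SE 0.20) and Hoxa3 (at least 23.7-fold). The calcium-binding protein S100b (2.77, SE 0.40) and the receptor Ntsr2 (2.28, SE 0.19) were also higher in the pons, and the organic anion transporter Slco1c1 was lower (-4.46, SE 0.19). Irx5 lies on chromosome 8 from 92357625 to 92376286, Hoxa2 on chromosome 6 from 52162417 to 52164831 and Pdgfra on chromosome 5 from 75152292 to 75198215, all protein-coding (mm10).

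**Figure D2:**
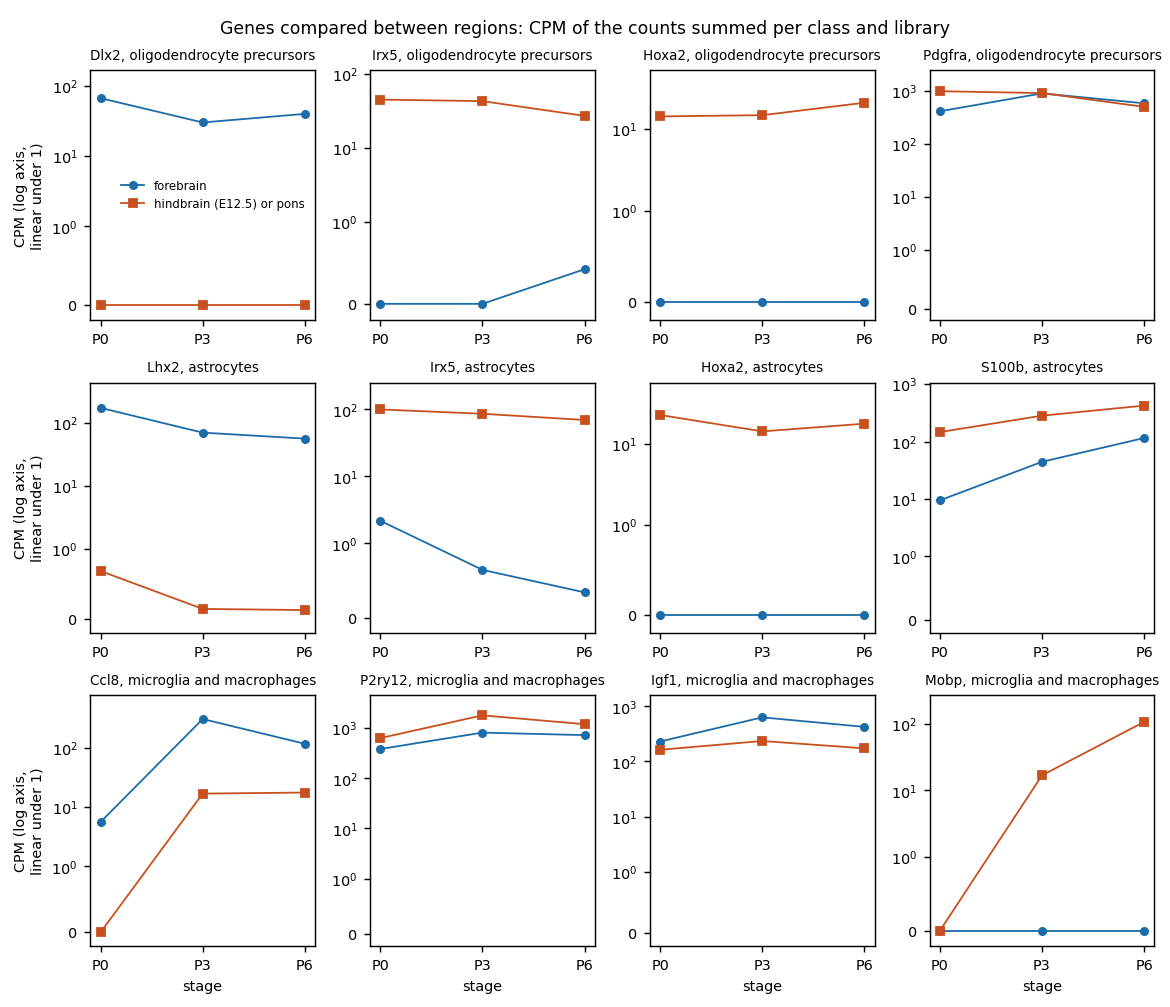
CPM of counts summed per class and library for 4 genes in oligodendrocyte precursors, astrocytes, and microglia and macrophages at P0, P3 and P6 (log axis, linear under 1), with circles for the forebrain and squares for the pons. Dlx2 of the precursors is at 0 in every pons library, while Pdgfra of the precursors differs by less than its spread over stages.

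In the astrocytes 1132 genes were higher in the pons and 920 in the forebrain, of 12846 tested. Of 21 forebrain factors 18 were lower in the pons (19 adjusted over the list alone, with 1 higher; fry adjusted p = 0.048, adjusted p = 0.16 with an estimated correlation), and of 15 hindbrain and midbrain factors 13 were higher (14 adjusted over the list alone; fry adjusted p = 0.033, adjusted p = 0.15 with an estimated correlation). S phase genes were lower in the pons for 11 of 39 (19 adjusted over the list alone; fry adjusted p = 0.048, adjusted p = 0.31 with an estimated correlation), with Cdca7 at -2.33 (SE 0.23). Of 46 G2M genes 20 were lower and the list did not pass (26 adjusted over the list alone; fry adjusted p = 0.10), Mki67 at -1.23 (SE 0.24) and Top2a at -1.11 (SE 0.19). They stood at 8.42% and 5.64% of their level in the rest of the library, Top2a within the level that RNA from other cells reached. Of 21 astrocyte maturation genes 10 were higher in the pons (13 adjusted over the list alone; fry adjusted p = 0.23). Of 24 tumour genes 4 were higher and 5 lower (6 and 6 adjusted over the list alone), Ntrk2 (0.74, SE 0.14) and Ntrk3 (0.95, SE 0.11) among the first and Gsx2 and Eomes, which the forebrain list also holds, among the second. Markers of oligodendrocytes were higher in the pons for 5 of 7 (median log2 2.73), Mbp at 11.7% of its level in the rest of the library, and markers of vascular leptomeningeal cells for 5 of 5 (median log2 2.09). Markers of inhibitory neurons were lower for 3 of 6 (median log2 -3.68), of intermediate progenitors for 2 of 4 and of excitatory neurons for 2 of 5. Myelin genes were higher for 9 of 11 (11 adjusted over the list alone; fry adjusted p = 0.17). The gene count was 593 without P3, 1069 without P0 and 596 with no stage term.

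In the microglia and macrophages, the immune cells of the brain and its borders, P2ry12, a purine receptor of resting microglia, was higher in the pons (1140 against 624 CPM, log2 0.89, SE 0.12, n = 3 stages, adjusted p = 0.0029, edgeR). The chemokine Ccl8 (-3.37, SE 0.30), the lectin Lgals3 (-1.51, SE 0.15) and the growth factor Igf1 (-1.05, SE 0.18) were higher in the forebrain. Socs3 (1.66, SE 0.27) and Casp4 (1.62, SE 0.27) were higher in the pons. The class pools microglia and macrophage clusters, at 119 and 74 cells in the P0 forebrain, 114 and 96 in the P0 pons, 80 and 71 in the P3 forebrain, 181 and 65 in the P3 pons, 265 and 45 in the P6 forebrain and 178 and 108 in the P6 pons, so genes of either kind can follow the mix. In all 59 genes were higher in the pons and 54 in the forebrain, of 9685. Transcripts of other classes were among them. Mobp, a myelin gene, was at least 71-fold higher in the pons at 11.6% of its level in the rest of the library and within the level of RNA from other cells, and 8 of 10 myelin genes tested were higher (10 adjusted over the list alone; fry adjusted p = 0.28). Of 8 forebrain factors 5 were lower in the pons (7 adjusted over the list alone; fry adjusted p = 0.048, adjusted p = 0.14 with an estimated correlation). RNA of other cells amounted to 4.58% to 20.93% of its level outside the class at P0 to P6, and 22 of the 113 genes lay within that level. Of 12 homeostatic genes 2 were higher (6 adjusted over the list alone; fry adjusted p = 0.28), and of 11 phagocytic genes 1 was higher and 3 lower (1 and 4 adjusted over the list alone; fry adjusted p = 0.23). With no stage term edgeR called 0 genes (303 at an unadjusted p under 0.05), and DESeq2 with the stage term called 57.

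Endothelial cells differed in fewer genes, 53 higher in the pons and 31 in the forebrain of 9577. Gkn3, a gene of arterial endothelium, was higher in the pons (log2 2.78, SE 0.31, n = 3 stages, adjusted p = 0.0007, edgeR). The P6 pons class includes a separate cluster of 35 cells with Gkn3 among its top 10 genes. The forebrain libraries have no counterpart to it, so differences can follow it. Plvap, a component of the diaphragms of permeable vessels, was lower (-3.09, SE 0.33) as the single call among 16 blood-brain barrier genes (1 adjusted over the list alone; fry adjusted p = 0.79), and the imprinted Mest was lower as well (-0.99, SE 0.13). Mbp (4.78, SE 0.17) was higher at 10.2% of its level in the rest of the library, and Tubb3, a neuronal tubulin, was lower at 12.8% of it. With no stage term edgeR called 0 genes (268 at an unadjusted p under 0.05), and DESeq2 with the stage term called 43. The count was 34 without P3 and 131 without P6.

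Progenitors and inhibitory neurons are given with less weight, since clusters led by markers of other classes held 25.7% and 19.4% of their cells, all progenitors of the P6 forebrain and P0 pons among them. In the progenitors Emx1, a factor of the cortex, stood at 110 CPM in the forebrain against 1 count (ratio at most 0.005 by counting error), and Cyp26b1 (8.94, SE 0.83) and Pax3 (7.83, SE 0.76) were higher. Pdgfra (1.56, SE 0.79, adjusted p = 0.30) and Mki67 (-0.96, SE 0.75, adjusted p = 0.50) did not pass. Counts were 203 higher and 90 lower over 5 stages, and 288 and 204 without those clusters over 3 stages, with 170 genes shared. The planned fit called 52 genes without E12.5, 74 without E15.5, 129 without P3 and 128 without P6. Of 19 forebrain factors 12 were lower (16 adjusted over the list alone; fry adjusted p = 0.033, adjusted p = 0.10 with an estimated correlation). Of 24 hindbrain and midbrain factors 16 were higher (21 adjusted over the list alone; fry adjusted p = 0.08). Markers of inhibitory neurons, which share Dlx genes with the forebrain list, were lower for 3 of 7 (median log2 -0.87), and markers of oligodendrocytes were higher for 3 of 6 (median log2 2.29). The mitochondrially encoded genes passed as a list with no single call (2 adjusted over the list alone; fry adjusted p = 0.048, adjusted p = 0.58 with an estimated correlation).

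In the inhibitory neurons Dlx2 and Dlx5 were at least 3230-fold and 2600-fold lower in the hindbrain or pons, where both were at 0 counts. En1, a midbrain and hindbrain factor, stood at 212 CPM against 2 forebrain counts (lower end of the ratio's counting interval 419.957), and Tfap2b at 86.6 CPM against 2 (lower end 171). Counts were 246 higher and 138 lower, and 183 and 101 without the clusters led by other markers, with 243 genes shared. Of 22 forebrain factors 17 were lower (17 adjusted over the list alone, with 2 higher), and of 22 hindbrain and midbrain factors 16 were higher (20 adjusted over the list alone), and neither list passed (fry adjusted p = 0.23 and 0.14). The planned count was 109 without E12.5, 76 without E15.5 and 2594 without P0. Over all classes 8 of 92 list tests of region passed with fry and 0 with camera, and with a stage left out 0 (E12.5, E15.5), 1 (P0, P6) or 2 (P3) list tests passed, those without P3 being both patterning lists of the oligodendrocyte precursors. Phagocytic microglia (smallest fry adjusted p 0.08), cholesterol synthesis (smallest fry adjusted p 0.13), dissociation stress (0.28), chromatin and histone H3 (0.067), fetal heterochronic (0.12), synaptic (0.072), blood-brain barrier (0.14) and pediatric brain tumour genes (0.13) passed in no class. HOX genes had fewer than 5 tested members in every class and gave no list test.

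The third comparison was of change over stages within a class. In the astrocytes the glial receptor Gpr37l1 rose by 1.80 (SE 0.30) on the log2 scale per stage step from P0 to P6, Myoc rose by 3.46 (SE 0.42), and Ntsr2 by 1.28 (SE 0.12), n = 6 libraries (edgeR adjusted p = 0.022, 0.012 and 0.0053). Igf2bp1, an RNA-binding protein of fetal tissues, fell by 2.19 (SE 0.29) and Igfbpl1 by 1.38 (SE 0.12). The ribosomal gene Rps27rt fell by 1.73 (SE 0.11), and such copies of ribosomal genes share reads with their parents, so this value is uncertain. Counts were 307 rising and 311 falling, in all 90 without P0 and 1491 without P6. Phagocytic microglia genes (9 tested, 1 rose, 4 adjusted over the list alone, the lipase Lpl at 1.77; fry adjusted p = 0.036, adjusted p = 0.21 with an estimated correlation) and mitochondrially encoded genes (13 tested, 1 rose, 9 adjusted over the list alone; fry adjusted p = 0.033, adjusted p = 0.27 with an estimated correlation) rose as lists. Tumour genes fell as a list (24 tested, 1 rose and 2 fell, 1 and 6 adjusted over the list alone, Olig2 at -0.80; fry adjusted p = 0.046, adjusted p = 0.33 with an estimated correlation). Mbp rose at 11.1% of its level in the rest of the library and within the level of RNA from other cells. Markers of oligodendrocytes rose for 6 of 7 (median log2 1.61 per step) and of erythroid cells for 3 of 5 (1.13), and markers of excitatory neurons fell for 3 of 5 (-2.01) and of intermediate progenitors for 2 of 4.

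Progenitors held 1295 rising and 1133 falling genes over E12.5 to P6. The clusters behind the class change with stage, and slopes can follow that change. In the forebrain they were mostly radial glia at E12.5 and E15.5, 1 cycling cluster at P0 and at P3 (121 and 273 cells, 68.6% and 64.5% named glial progenitors in the joint labels) and 1 of 631 cells at P6 (55.9% named inhibitory intermediate progenitors). In the pons they were 100 cells at P0 (50% named oligodendrocyte precursors), 171 at P3 and 442 at P6 (56.1% named glial progenitors). The water channel Aqp4 (log2 2.81 per step, SE 0.45, n = 10 libraries, edgeR adjusted p = 0.0051), Gpr37l1 (2.93, SE 0.35), the angiotensinogen Agt (2.69, SE 0.51) and Apoe (2.49, SE 0.53) rose, and Igf2bp1 (-1.54, SE 0.11), the chromatin protein Hmga2 (-1.37, SE 0.33) and Crabp2 (-1.77, SE 0.26) fell, and of these Hmga2 alone lost its call without the clusters led by other markers (-1.22, adjusted p = 0.058). Pdgfra rose by 1.36 (SE 0.32). Of 21 astrocyte maturation genes 17 rose and 1 fell (19 and 1 adjusted over the list alone; fry adjusted p = 0.012, adjusted p = 0.24 with an estimated correlation), of 10 myelin genes 8 rose (10 adjusted over the list alone; fry adjusted p = 0.012, adjusted p = 0.23 with an estimated correlation), and of 9 fetal heterochronic genes 5 fell (1 rose and 5 fell adjusted over the list alone; fry adjusted p = 0.0018, adjusted p = 0.19 with an estimated correlation). Dissociation stress genes rose for 7 of 16 and fell for 1 (9 and 1 adjusted over the list alone; fry adjusted p = 0.0018, adjusted p = 0.19 with an estimated correlation), Junb at 1.32 and Nr4a1 at 1.27 against Jund at -0.53. Mitochondrially encoded (10 of 13 rose, fry adjusted p = 0.0018), phagocytic (6 of 8, 0.0018), homeostatic microglia (3 of 8, 0.036) and blood-brain barrier genes (3 of 12, with 1 falling, 0.044) rose as lists and chromatin genes (2 of 11 fell, 0.012) fell. The median mitochondrial percent of cells, a sign of cell quality, also rose in the whole libraries, from 2.117% at E12.5 to 5.698% at P6 in the forebrain and from 3.008% to 5.478% in the hindbrain and pons (3.303% at P0), so the mitochondrial lists of this class, astrocytes and microglia can follow it. Adjusted over the list alone the list counts were 10, 6, 4, 5 with 1 falling, and 2, and the lists had adjusted p = 0.24, 0.19, 0.37, 0.38 and 0.27 with an estimated correlation. Spp1 and Cldn5 of these lists lay within the level of RNA from other cells. Clusters led by other markers held 25.7% of the cells, and the fit without them called 2857 genes, 2057 of them shared. Markers of astrocytes rose for 5 of 6 and of oligodendrocytes for 6 of 6, and markers of neural progenitors rose for 1 and fell for 4 of 9. Markers of endothelial cells rose for 3 of 5 (median log2 1.14 per step) and of inhibitory neurons for 3 of 6 (0.65). Markers of excitatory neurons fell for 1 of 4.

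**Figure D3:**
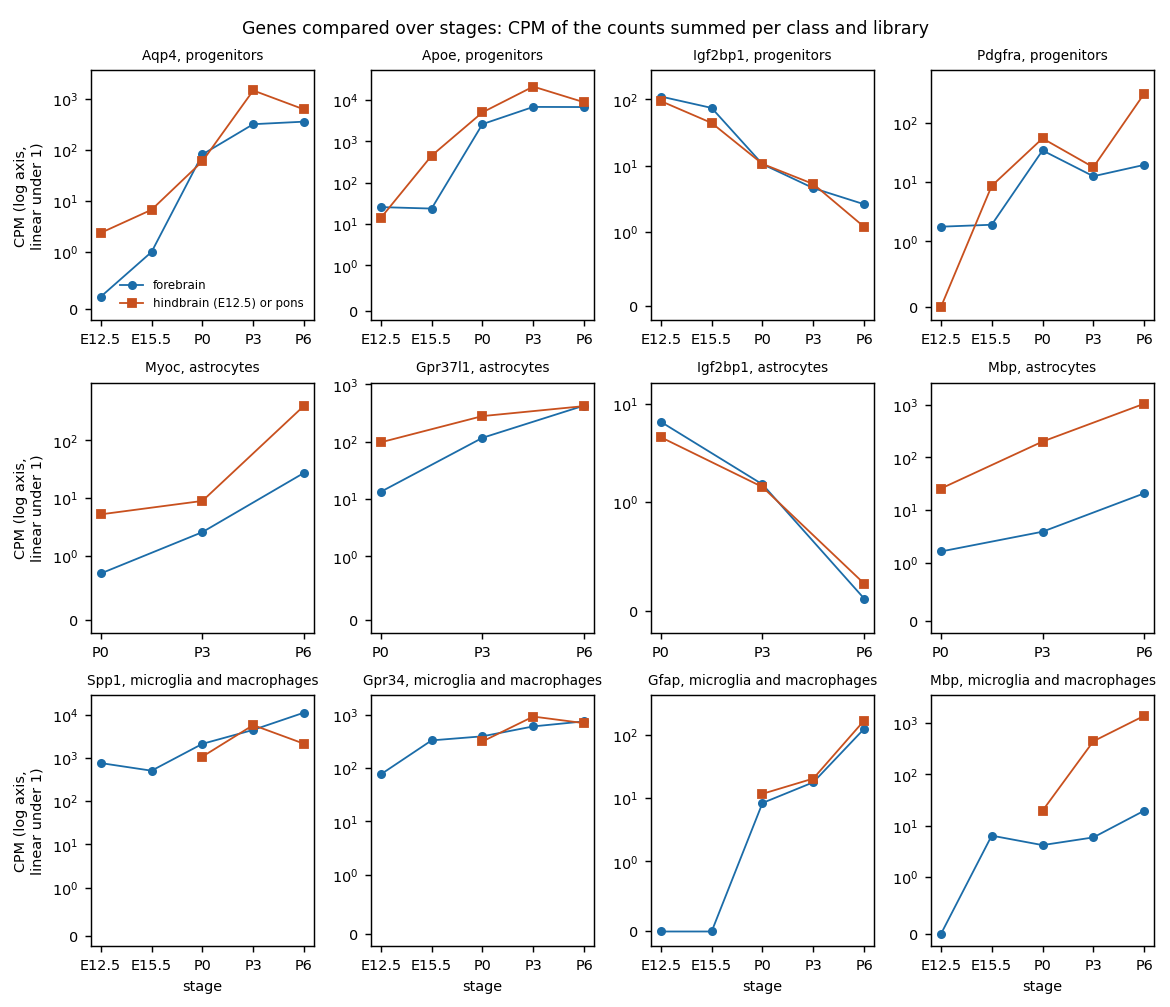
CPM of counts summed per class and library for 4 genes in progenitors, astrocytes, and microglia and macrophages by stage (log axis, linear under 1), with circles for the forebrain and squares for the hindbrain (E12.5) or pons, and no point where a library had under 20 cells of the class. Igf2bp1 of the progenitors falls by 1.54 on the log2 scale per step, while Gfap and Mbp of the microglia lie within the level of RNA from other cells.

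In the microglia and macrophages the osteopontin gene Spp1 rose by 1.0 (SE 0.20) on the log2 scale per step, Gpr34, a receptor of homeostatic microglia, by 0.63 (SE 0.14) and Junb by 0.77 (SE 0.12), n = 8 libraries (edgeR adjusted p = 0.015, 0.013 and 0.0015). The class pools both kinds, and slopes can follow their mix. Its embryonic libraries are of the forebrain alone, with 30 cells at E12.5 (63.3% named macrophages in the joint labels) and 22 at E15.5 (54.5% named microglia). The P6 forebrain held 265 microglia and 45 macrophages. Counts were 305 rising and 53 falling, or 251 and 184 with a minimum of 50 cells, which leaves out the embryonic libraries (233 genes shared), with 2 pseudogenes of ribosomal proteins (Rps26-ps1, Rpl7a-ps5) and 2510039O18Rik as the largest decreases. The largest increases were Mbp (2.12, SE 0.44), Gfap (2.01, SE 0.18) and Aqp4 (1.98, SE 0.20), markers of oligodendrocytes and astrocytes, at 19.7%, 14.2% and 19.7% of their level in the rest of the library and within the level of RNA from other cells, as were 108 of the 358 genes. Astrocyte maturation genes rose for 16 of 20 (18 adjusted over the list alone; fry adjusted p = 0.036, adjusted p = 0.19 with an estimated correlation). Mitochondrially encoded genes rose as a list (13 tested, 1 rose, 7 adjusted over the list alone; fry adjusted p = 0.031, adjusted p = 0.24 with an estimated correlation). Cholesterol synthesis genes rose for 8 of 17 and did not pass as a list (13 adjusted over the list alone; fry adjusted p = 0.083). In the progenitors and astrocytes no cholesterol list passed either (fry adjusted p = 0.21 and 0.16). The share of RNA from other cells was 13.58% in the E12.5 forebrain, 2.38% at E15.5, 8.60% at P0 and 20.93% at P6. The count was 190 without P0 and 95 without P6, and with embryonic against postnatal stages in place of the order edgeR called 0 genes.

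In the endothelial cells 75 genes rose and 60 fell over 8 libraries, or 58 and 98 with a minimum of 50 cells over 6 libraries (50 genes shared). The embryonic libraries were 29 cells of the E12.5 forebrain and 27 of the E15.5 pons, each without the other region. Pf4, a macrophage marker, was first among the top 10 genes of the E12.5 cluster, so falling genes can follow it. Of 2 macrophage markers tested 0 passed (median log2 -1.45 per step). The transferrin receptor Tfrc rose by 0.72 (SE 0.12) as the single call among 15 blood-brain barrier genes (4 rose and 1 fell adjusted over the list alone; fry adjusted p = 0.072), and the imprinted Plagl1 fell by 1.04 (SE 0.16) and Dapk3 by 1.08 (SE 0.22). Igf2bp1 fell by 1.53 (SE 0.22), and the fetal heterochronic genes fell as a list (8 tested, 1 fell, 1 adjusted over the list alone; fry adjusted p = 0.034, adjusted p = 0.19 with an estimated correlation). Mbp (2.65, SE 0.24) rose within the level of RNA from other cells, and the embryonic globin Hbb-y fell by 3.03 (SE 0.45), with the haem enzyme Alas2 rising by 1.89 (SE 0.22); both are markers of erythroid cells. The count was 35 without E12.5, 319 without P0, 6 without P3 and 5 without P6.

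Oligodendrocyte precursors had 1 rising and 1 falling gene from P0 to P6 (1219 at an unadjusted p under 0.05, and 115 genes by DESeq2), Mobp at 3.23 (SE 0.27) and Rps27rt at -1.69 (SE 0.18), and their fetal heterochronic genes fell as a list with no single call (9 tested, 3 fell adjusted over the list alone; fry adjusted p = 0.011, adjusted p = 0.19 with an estimated correlation). Pdgfra (-0.15, SE 0.21, adjusted p = 0.83) and Olig2 (-1.21, SE 0.14, adjusted p = 0.053) did not pass. The count was 421 without P3 and 490 without P6. In the inhibitory neurons 176 genes rose and 148 fell, or 103 and 91 without the clusters led by other markers. The Purkinje cell protein Pcp4 (1.94, SE 0.29) and the glutamate receptor subunit Grin1 (1.64, SE 0.19) rose, and the factor Lhx1 (-2.52, SE 0.38) fell, and each kept its call without those clusters. The clusters behind the class change with stage, and slopes can follow that change. Lhx1 was among the top 10 genes of clusters of 407 cells in the E12.5 hindbrain and 924 in the E15.5 pons. At P0 the pons class was a cluster of 119 cells alone. The planned count was 7 without E12.5, 63 without E15.5 and 1435 without P0. Of 21 synaptic genes 5 rose (10 adjusted over the list alone; fry adjusted p = 0.0035, adjusted p = 0.19 with an estimated correlation). In all 17 of 94 list tests of stage passed with fry and 0 with camera. Patterning factors, S phase and G2M genes passed in no class, with smallest fry adjusted p of 0.11 for forebrain factors, 0.059 for hindbrain and midbrain factors, 0.17 for S phase and 0.41 for G2M.

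The labels carry 2 kinds of library names, 1 for E12.5 to P0 and another for P3 and P6, so stage goes together with the series of libraries. With that series as a term edgeR called 0 genes in the progenitors (1786 at an unadjusted p under 0.05) and 0 in the oligodendrocyte precursors (1156), 37 in the astrocytes, 8 in the microglia and macrophages and 5 in the endothelial cells; DESeq2 was not run with it. Without E12.5 the progenitor count was 17, without E15.5 898 and without P3 1375.

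The slopes of the regions were then set against each other. edgeR called 1 gene in the progenitors, Mobp, and 1 in the astrocytes, Xist, and 0 in the inhibitory neurons, oligodendrocyte precursors, microglia and endothelial cells (778, 320, 228 and 298 at an unadjusted p under 0.05, and 43, 0, 0 and 0 by DESeq2). DESeq2 called 55 genes in the progenitors and 14 in the astrocytes. Mobp lost its call without E12.5, E15.5, P3 or P6 and kept it without P0. The edgeR count of the progenitors was 0 without E12.5, E15.5 or P3, 1 (another gene) without P6 and 2 without P0, that of the microglia 8 without P0 and 1 without P6, and that of the endothelial cells 3 without P0. No list passed of 94 tested with fry, nor with camera.

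The last account is of where transcripts of childhood brain tumour genes were found, with no test. Each class was averaged over its own set of libraries, such as 6 for astrocytes, 7 for ependymal cells, 10 for progenitors and 3 for intermediate progenitors. The order of classes can therefore follow stage and region. Pdgfra, altered in high-grade gliomas, averaged 710 CPM in the oligodendrocyte precursors (409 to 979 CPM over 6 libraries) and 140 CPM in the next class, vascular leptomeningeal cells; it is also a marker by which the precursors are known. Ntrk2, a neurotrophin receptor, was highest in astrocytes (603 CPM, 362 to 759) and close to that in ependymal cells (561 CPM). Ptch1, the hedgehog receptor, averaged 103 CPM in astrocytes, with 173 CPM in the P0 pons (Poisson interval 161 to 186) and 62.1 CPM in the P6 forebrain. Fgfr1 averaged 116 CPM in astrocytes, Ntrk3 82.1 CPM in the precursors, Mycn 103 CPM in excitatory neurons (34.6 to 172) and Acvr1, a BMP receptor, 17.5 CPM in endothelial cells (11.7 to 27.1). The next classes were close. Fgfr1 averaged 98.0 CPM in vascular leptomeningeal cells, Ntrk3 71.0 CPM in astrocytes, Mycn 87.2 CPM in progenitors and Acvr1 12.8 CPM in ependymal cells. Eomes (273 CPM) was highest in intermediate progenitors and Barhl1 in other neurons, with 0 to 723 CPM between libraries. Clusters led by markers of other classes held 28.7% of the excitatory neurons and 31.3% of the intermediate progenitors. The intervals cover counting error only.

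**Figure D4:**
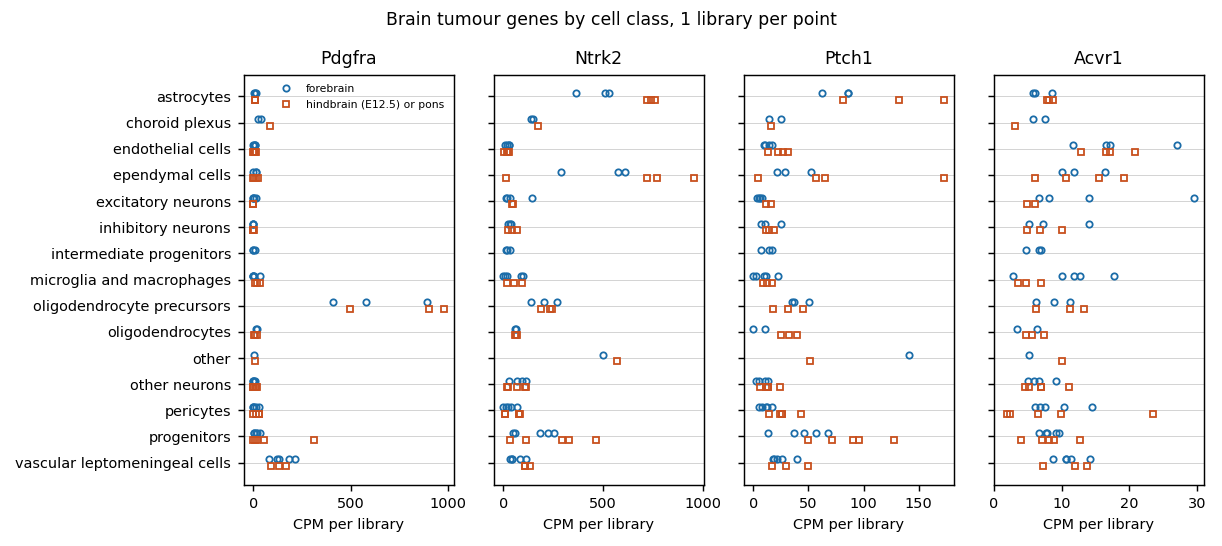
CPM per library of Pdgfra, Ntrk2, Ptch1 and Acvr1 in each cell class, with circles for the forebrain and squares for the hindbrain (E12.5) or pons. Pdgfra of the oligodendrocyte precursors lies between 409 and 979 CPM in each of 6 libraries.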

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

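The tests of RNA from other cells, of doublets, of sex, of stage orders that keep libraries together and with the library series as a term were chosen only after the data were seen. Slopes over stages differed between the regions for 2 genes. In the progenitors the slope of Mobp, a myelin gene, was 4.59 higher in the hindbrain and pons than in the forebrain (log2 per step, SE 0.41, edgeR adjusted p = 0.0058), a call lost without E12.5, E15.5, P3 or P6 and kept without P0. In the astrocytes the slope of Xist was 20.22 higher (SE 1.36, edgeR adjusted p = 0.015), and in the whole libraries Xist stood at 1714.0 CPM in the forebrain and 0.8 CPM in the pons at P0, and at 0.4 and 1007.4 CPM at P6. The Y-linked Ddx3y stood the other way, at 0 and 87.9 CPM at P0 and at 84.2 and 0 CPM at P6, so the slope of Xist follows the sex of the animals, and its size rests on libraries near 0 counts; DESeq2 did not call it.

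Transcripts of neurons, astrocytes and oligodendrocytes were among the genes called in microglia and endothelial cells. For microglia and macrophages 19.5% of the region genes and 30.2% of the stage genes lay within the level that RNA from other cells reached, and for endothelial cells 9.5% and 17.8%, which leaves such RNA, free or in doublets, open as a source. Genes above the level in only some libraries of the higher side are not in these percentages. Without the top 5% of doublet scores the region differences of these genes kept 0.79 of their size in the microglia (0.47 to 1.04 over genes) and 0.90 in the endothelial cells (0.61 to 1.31), so doublets with high scores cannot be told apart from free RNA by this test. Expression by the cells themselves was not tested.

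Patterning factors differed between regions in progenitors, inhibitory neurons, oligodendrocyte precursors and astrocytes. Free RNA at the measured share is argued against as the whole source of the factors higher in the forebrain. Of these 0 of 12, 0 of 17, 0 of 12 and 0 of 18 (0% in each class) lay within its level in every forebrain library. Each thus lay above it in some library, and not necessarily in all. The same holds for those higher in the hindbrain or pons in progenitors (1 of 18, 5.6%, over 3 of 5 libraries with a measured share) and astrocytes (0 of 17). In the precursors (0 of 7) the factors were too few to bound the share closely. For inhibitory neurons (2 of 19, 10.5%) 1 library had a measured share and this stays open. The share rests on immune, vascular, leptomeningeal and choroid plexus markers. Doublets with neurons, or neural cells of another class among those labelled, were therefore not measured and stay open. Over the stages with sex-linked genes alike in both regions, 91.1% (41 of 45) of all tested factors, called or not, differed in the direction their list names in progenitors, 91.7% (44 of 48) in inhibitory neurons, 91.7% (22 of 24) in precursors and 95% (38 of 40) in astrocytes (P3 alone in the latter pair), which argues against sex as the cause. Calls of precursors and astrocytes shared 39 genes higher and 57 lower in the pons, against 5.3 and 7.6 for independent lists, and part of that may come from the libraries they share. Other pairs also shared more than independent lists would. Microglia and endothelial cells shared 9 higher and 12 lower (0.2 and 0.1), and precursors and microglia 25 lower (0.5). Inhibitory neurons and endothelial cells shared 0 higher (0.3). Sharing is thus not particular to precursors and astrocytes. Regional identity of the cells stays a hypothesis, with dissection untested.

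Stage goes together with the library series, which changed between P0 and P3. In the progenitors 97.6% of the called genes moved in the direction of their slope within E12.5, E15.5 and P0 (lower limit 96.9%), against 74.8% in data simulated with a step between the series alone (75.4% at most), which argues against such a step as the whole cause. That limit takes genes as independent, and with the series as a term 0 genes were called (8 and 5 in microglia and endothelial cells), so how much of each slope the series gives stays open. In the microglia (81.6%, lower limit 77.2%) and endothelial cells (98.5%, lower limit 94.8%) slopes cannot be told apart from the series, since the step alone gave 80.0% (88.1% at most) and 93.0% (94.2% at most) over 4 early libraries, so the bound set in advance for excluding it lay below what a step gives, and the small excess in endothelial cells takes genes as independent. Age stays open as the other explanation, untested.

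Other arrangements of the same libraries were counted. For the region genes of the progenitors 1 of 60 drawn splits (of 126) gave as many genes as the real 293, itself, with 40 as the highest of the others. The libraries pair by stage, however, and 16 splits part both libraries of every stage (highest other 0), too few for a share under 0.05. Each of the other classes has 10 splits, too few for a share under 0.05; 1 of the 10, the real one, gave as many in each, with real values and highest others of 384 and 0 for inhibitory neurons, 191 and 1 for oligodendrocyte precursors, 2052 and 0 for astrocytes, 113 and 8 for microglia and 84 and 36 for endothelial cells. For the stage genes 1 of 60 drawn orders gave as many in the progenitors (2428, highest other 2), microglia (358, highest other 356) and endothelial cells (135, highest other 11). Of the 60 orders that keep the libraries of a stage together 2 gave as many in the progenitors (highest other 3367), 5 in the microglia (557) and 1 in the endothelial cells (95). Both shares lay under 0.05 in progenitors and endothelial cells, but not in microglia. In the progenitors another order gave more genes than the real one, and with 1 library per region and stage such shares do not exclude chance. The 18 orders of the remaining classes, 3 of which keep stages together, are too few for a share under 0.05, with 324 and 0 for inhibitory neurons and 618 and 1 for astrocytes (1 of 18 in each). For oligodendrocyte precursors 2 of 18 orders gave 2 genes or more, and the highest other gave 105, which points to a structure of the samples that was not tested.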

How the results depend on the processing

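Tests with the joint labels, with the authors' left-out clusters, without clusters led by other classes, without the top 5% of doublet scores, without genes within the level of RNA from other cells and with the library series were chosen only after the data were seen; the others were fixed in advance. The cause of the changes was not tested unless stated. Of the named genes of the region comparison 131 of 145 kept their call with DESeq2 and 56 of 131 with no stage term, and no setting reversed any of them. Of those of the stage comparison 115 of 122 kept it with DESeq2 and 5 of 106 with the library series. RLE size factors kept 145 of 145 and 119 of 122. The libraries pair by stage alone, and stage was the block of the region fits. The later updated labels also leave out 66.6% of the cells of the E15.5 pons, 39.9% of the E12.5 hindbrain and 20.7% of the E12.5 forebrain.

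The numbers of region genes were, for progenitors (293 as planned), 937 with DESeq2, 576 with the later updated labels, 59 with no stage term, 1480 with the left-out clusters, 982 with the joint labels and 492 without clusters led by other classes. For inhibitory neurons (384) they were 827 with no filter on low counts, 803 with DESeq2, 129 with the updated labels, 104 with no stage term and 1168 with the left-out clusters. For oligodendrocyte precursors (191) they were 562 with no filter, 60 with no stage term, 97 with stage order as a linear term and 986 with the joint labels. For astrocytes (2052) the number was 596 with no stage term. For microglia and macrophages (113) they were 419 with no filter, 57 with DESeq2, 0 with no stage term in edgeR (303 at an unadjusted p under 0.05), 34 with the linear term and 75 without the top 5% of doublet scores. For endothelial cells (84) they were 330, 43, 0 (268 unadjusted) and 11 in the same order, and 158 with the joint labels.

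The numbers of stage genes were, for progenitors (2428), 3761 with DESeq2, 1067 with thinned counts, 4337 with the joint labels and 0 with the library series. For inhibitory neurons (324) they were 1140 with no filter, 1050 with DESeq2, 0 with no region term, 63 with embryonic against postnatal stages, 496 with the left-out clusters and 194 without clusters led by other classes. For oligodendrocyte precursors (2) they were 4 with RLE, 197 with no filter, 115 with DESeq2, 0 without Scrublet's doublets, 27 with thinned counts, 0 with no region term, 281 with the joint labels, 5 without the top doublet scores and 0 with the series. For astrocytes (618) they were 956 with DESeq2, 0 with no region term, 1030 with the joint labels and 37 with the series. For microglia and macrophages (358) they were 96 with thinned counts, 0 with embryonic against postnatal stages and 8 with the series. For endothelial cells (135) they were 310 with no filter, 391 with DESeq2, 80 with thinned counts, 224 with embryonic against postnatal stages and 5 with the series. With no region term 1948, 1068 and 1864 genes of the inhibitory neurons, precursors and astrocytes had an unadjusted p under 0.05. A minimum of 50 cells gave 251 rising and 184 falling genes in microglia (305 and 53 as planned) and 58 and 98 in endothelial cells (75 and 60).

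For the difference between slopes no filter gave 2, 250, 20, 93, 10 and 5 genes in progenitors, inhibitory neurons, precursors, astrocytes, microglia and endothelial cells. DESeq2 gave 55, 43 and 14 in progenitors, inhibitory neurons and astrocytes, and thinned counts gave 0 and 5 in the progenitors and inhibitory neurons. Directions that turned were those of Sqle in progenitors over stages (-0.09 with the series), Eomes (0.13 with the series, and from -3.42 without P6 to 0.11 without P0) and H19 (0.11 with the series, and from -2.33 to 0.10 in the same omissions) in astrocytes, and Mobp in microglia (-0.46 with DESeq2).

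Leaving out each stage in turn gave 52 (E12.5) to 203 (P0) region genes in progenitors, 76 (E15.5) to 2594 (P0) in inhibitory neurons, 93 (P0) to 447 (P3) in precursors, 593 (P3) to 2852 (P6) in astrocytes and 34 (P3) to 131 (P6) in endothelial cells. Stage genes ranged from 17 (E12.5) to 2901 (P0), 7 (E12.5) to 1435 (P0), 1 (P0) to 490 (P6), 90 (P0) to 1491 (P6) and 5 (P6) to 319 (P0) in the same classes, and from 95 (P6) to 342 (E12.5) in microglia. Slope differences ranged from 0 to 2 in progenitors, 0 to 8 in microglia and 0 to 3 in endothelial cells. Lists ranged from 0 to 2 for region and from 6 to 10 for stage, and 0 passed in each with an estimated correlation. With 4 stages fewer arrangements exist, so trends of shares lose calls by construction. Their mean rho ranged from 0.84 to 0.95 for astrocytes, 0.90 to 1.0 for endothelial cells, 0.60 to 0.97 for ependymal cells, -0.87 to -0.57 for excitatory and -0.95 to -0.84 for inhibitory neurons. It ranged from 0.70 to 0.87 for microglia, 0.60 to 0.95 for precursors, 0.86 to 0.97 for oligodendrocytes, 0.70 to 0.90 for pericytes and 0.70 to 0.87 for vascular leptomeningeal cells. Only endothelial cells and oligodendrocytes kept their call in any omission, that of E12.5 or of E15.5 (adjusted p = 0.049).

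Without blood, vascular and immune classes in the denominator the trends of ependymal cells (0.74), excitatory neurons (-0.75) and precursors (0.77) had an adjusted p of 0.053. With the left-out clusters those of excitatory neurons (-0.69), precursors (0.77) and vascular leptomeningeal cells (0.73) had 0.072, 0.052 and 0.057. With the joint labels other neurons fell (-0.85, adjusted p = 0.019).

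List adjusted p values over the omissions ranged, for region, from 0.053 to 0.13 and 0.053 to 0.19 in progenitors (forebrain, mitochondrial), 0.041 to 0.19 for either patterning list in precursors, 0.17 to 0.23, 0.12 to 0.20 and 0.12 to 0.23 in astrocytes (forebrain, hindbrain and midbrain, S phase) and reached 0.21 without P0 in microglia. Only the lists of the precursors kept a call, that without P3. For stage 5 lists of the progenitors (fetal heterochronic, myelin, dissociation stress, phagocytic, mitochondrial) kept their call in every omission. The others of that class ranged from 0.0083 to 0.097 (astrocyte maturation, lost without E12.5), 0.0066 to 0.12 (chromatin, lost without E12.5 or P3), 0.0019 to 0.29 (homeostatic, lost without E12.5, P0 or P3) and 0.063 to 0.17 (blood-brain barrier, lost in all). In microglia astrocyte maturation (0.039 to 0.25) kept its call without E12.5 only and mitochondrial genes (0.042 to 0.14) without P0 only, and in endothelial cells fetal genes (0.050 to 0.59) without E15.5 only. Lost in every omission were fetal genes in precursors (0.073 to 0.13), synaptic genes in inhibitory neurons (0.061 to 0.17) and, in astrocytes, phagocytic (0.12 to 0.25), mitochondrial (0.22 to 0.37) and tumour genes (0.34 to 0.41).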

Other observations

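The values below were looked at only after the data were seen, and no tests were made of them. Some sub-clusters of the E12.5 hindbrain and E15.5 pons carry labels that changed between the authors' first and later deposited annotation. The cells first labelled as glial progenitors (93 at E12.5 and 206 at E15.5) bear a neuronal progenitor label later. They held Tubb3, a neuronal tubulin, at 1880 and 2700 CPM and Fabp7, a radial glial gene, at 1560 and 820.0 CPM. The 32 and 273 cells that bear the glial progenitor label later held Fabp7 at 13100 and 18000 CPM and Tubb3 at 328 and 686 CPM. A set of 228 and 61 cells went from a neuronal progenitor label to a radial glial label, with Top2a at 890.0 and 708 CPM and Fabp7 at 5640 and 5880 CPM.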
